A study of Homo sapiens with 288 samples.

How the data were processed

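The series holds single-cell RNA sequencing of human embryonic stem cells, with 1 deposited file per cell and 288 files in all. Groups were taken from the labels: the titles mark an experiment with late passage naive cells, an experiment with early passage naive cells and an experiment with differentiated cells. In 1 library the title gives late passage and the source gives differentiated cells; it was left out of the main comparisons and added to late passage in 1 alternative.

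The values are whole-number read counts per gene, as the authors deposited them. Reads were aligned with TopHat2 2.1.0 to the hg19 genome build and counted with HTSeq 0.6.1p1, per the submitters' processing notes. The gene annotation, the strand setting, read trimming and any filter on cells are not given in the sources used here. Each file lists 26364 genes for differentiated cells and 26363 for naive cells; TSIX is the gene that only the differentiated files list. No mitochondrial gene is listed. The 5 summary lines of each file, which name no gene, stayed out of all totals. Reads not on a named gene make up 3.52% of the reads in the files, of which 6167489 are ambiguous. Only 9150 reads are listed as aligned in several places, so genes with near-identical copies (GAPDH, POU5F1, KRT8, KRT18, DPPA3, the metallothioneins, ribosomal protein genes) are uncertain. Without a stated strand setting, reads of antisense or overlapping genes cannot be told apart.

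Chromosomes were assigned by gene symbol from RefSeq genes of GRCh38.p14; 23629 symbols matched directly, 1569 through a synonym of 1 gene, and 1166 stayed unmatched, with 0.469% of gene reads. Since the counts come from another build, no coordinate is printed, and the reference served for names, chromosomes and gene order. The overlap of XIST and TSIX was measured in GENCODE 29. X-linked means on the X outside the pseudoautosomal regions and without XIST. Genes on the Y chromosome are not reported.

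Cells with at least 100000 gene reads and 2000 genes were kept: 53 of 96 differentiated, 81 of 95 late passage and 87 of 96 early passage libraries. The pools held 21110440, 57495647 and 88299342 gene reads, and the deepest cell gave 8.38%, 9.92% and 5.58% of them. Median genes per kept cell were 5215, 7067 and 6533. No libraries were identical. No doublet caller was run, and capture images are not among the sources used here. A pool's floor for a gene without a read was set at 3 reads.

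As the labels name 1 culture per group, counts of kept cells were summed per group and scaled to CPM, and no model was fitted across genes. Ratios are log2 of CPM plus a pseudocount of 1, and folds marked "at least" set the group without a read at the floor. Such a bound covers the counting of reads only, not how well RNA of single cells was captured. The X shift is the median log2 ratio of X-linked genes minus that of autosomal genes, over genes with a mean of at least 10 CPM in the 3 pools, with a 95% order-statistic interval over genes. Gene lists used genes with a mean of at least 1 CPM; a list's percentile is the place of its median among 10000 random lists of the same size, each gene replaced by 1 of the 100 nearest in mean expression. Percentiles describe these libraries and are not p-values. Genes called at least 2-fold higher or lower have a ratio of 2 on that scale. Zero-count genes understate list medians: with them at the floor, the naive list's median was -6.83 against early and -5.77 against late passage. The autosomal median itself lay at -0.59 (differentiated against early), -0.37 (differentiated against late) and -0.17 (late against early passage). TMM factors moved it by 0.37, 0.14 and 0.24, and DESeq2 size factors by 0.57, 0.25 and 0.33.

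Genes named in the text follow a rule fixed before the data were examined: in each comparison the 12 genes with the highest and the 12 with the lowest log2 ratio, among genes with at least 20 CPM and a read in at least 30% of cells of the higher group, and the same direction in wells of columns 1 to 6 and 7 to 12 taken alone. XIST, Y-linked and mitochondrial genes and names starting with LOC, MIR, SNOR, SNAR or RNU were excluded. From each fixed list, the 2 to 4 members with the highest CPM were added. Other members named beside a count, such as MAEL, KLF17, FGF4, DPPA2, GDF3, PRDM14, SOX1, SOX2, KDM6A, LIN28A, BIRC5 and NEAT1, were chosen after their values were seen. The 19 lists covered naive, core and primed pluripotency, mesenchymal and fibroblast, neural, endoderm, early mesoderm, trophoblast, epithelial, endothelial and blood genes, imprinted genes, DNA methylation, X inactivation regulators, X-linked genes subject to inactivation or escaping it, the cell cycle, immediate early and stress genes, glycolysis and HOX genes.

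Shares of cells carry exact Clopper-Pearson intervals. Thinning drew 100000 reads per cell without replacement. A depth of 500000 reads left 9 differentiated, 35 late passage and 54 early passage cells. Clusters were made within groups from log2(CPM + 1) of the 1000 most variable genes, 10 principal components, 10 nearest neighbours and the Leiden method at resolution 1. Alternatives covered cell filters, weighting of cells, TMM and DESeq2 scaling, pseudocounts of 0.1 and 5, gene filters, wells by column, the 20 highest genes left out and the library with conflicting labels added to late passage.

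The scripts were tested on simulated counts drawn from the real means and depths, with extra variation between cells. A true X shift of -0.5 was recovered as -0.51, -0.53 and -0.51 in the comparisons of differentiated with early, differentiated with late and late with early passage, at percentile 0.0 each, while an unshifted autosomal list lay at percentile 33.0, 81.4 and 77.7. In the last comparison, 74 of 93 genes altered 2-fold and 72 of 107 altered 4-fold were recovered within 0.5 log2, among 7925 autosomal genes. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, the last pair for scaling factors only.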

Results

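Polyadenylated RNA of single human embryonic stem cells was sequenced after capture on a Fluidigm C1 microfluidic system. Per the labels, 288 libraries of 1 cell each fall into 3 groups: naive cells at an early passage (96 libraries), naive cells at a late passage (95 libraries) and cells differentiated from naive cells (96 libraries), while 1 library has labels that contradict each other and was placed in no group. Naive embryonic stem cells are held in a state like that of the preimplantation epiblast. After libraries with under 100000 gene reads or under 2000 genes were set aside, 87 early passage, 81 late passage and 53 differentiated cells remained. Their median depth was 675236, 400246 and 326365 gene reads, and kept cells held from 100564 to 5703021 gene reads. Of the 43 differentiated libraries left out, 16 held under 1000 gene reads. The labels name 1 culture per group and no cell line. They do not say whether the cells of a group came from several cultures or whether the groups share a line. Each group is therefore taken as 1 sample, no p-value was computed from cells, and no difference below has a replicate check. Group, culture and capture run cannot be told apart. Values are CPM, the reads of a gene scaled to the gene reads of the pooled cells, and their exact Poisson or Clopper-Pearson intervals (95%) cover counting error only, since no molecular identifiers are named in the labels.

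The first comparison asks how differentiated cells differ from naive cells. Transcripts that mark naive cells were lower in differentiated cells. Each of the 19 genes of the naive list stood at least 2-fold lower in differentiated than in early passage cells, and the same held against late passage cells. The list's median log2 ratio was -5.34 against early passage (order-statistic interval -7.88 to -4.49) and -5.46 against late passage (-7.54 to -4.45), below all 10000 random lists of matched expression in both comparisons (percentile 0.0). DPPA3, a factor of preimplantation cells that protects maternal methylation, stood at 1160 CPM in early passage (1153 to 1167), at 1909 CPM in late passage (1898 to 1920) and at 9.24 CPM in differentiated cells (7.99 to 10.6). DPPA5 (1165 and 1271 CPM in early and late passage), KHDC1L (1221 and 1137 CPM) and DNMT3L, a cofactor of de novo DNA methylation (1270 and 1068 CPM), had no read in any of the 53 differentiated cells, which allows up to 3 reads per pool. Against early passage and with that floor, DNMT3L was at least 8936-fold, KHDC1L at least 8591-fold and DPPA5 at least 8201-fold lower in reads. These bounds cover the counting of reads only.

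Core pluripotency genes were lower as well, in 12 of 15 against early and in 13 of 15 against late passage, and none was at least 2-fold higher. NANOG stood at 504 CPM in early passage, 654 CPM in late passage and 0.57 CPM (0.29 to 0.99) in differentiated cells, where 2 of 53 cells had a read. SOX2 had no read there, against 23.8 and 37.4 CPM. L1TD1 stood at 73.5 CPM against 497 and 639 CPM, and DPPA4 at 20.7 CPM against 264 and 483 CPM. TDGF1, a coreceptor of Nodal signalling, was an exception, with 471 CPM in differentiated cells, 389 CPM in early and 418 CPM in late passage. The median of the core list was -3.46 and -3.65 log2 (percentile 0.0 in both).

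Further genes lower in differentiated cells include metallothioneins, which bind zinc and copper. MT1G stood at 1159 CPM in early and 3680 CPM in late passage, and MT1H at 514 and 1810 CPM, with no read in differentiated cells. MT1X stood at 2.04 CPM against 1024 CPM in late passage. Close paralogs make the split of reads among metallothioneins uncertain. ALPPL2, a surface phosphatase of naive cells (303 CPM in early passage), CCNA1, a cyclin of germ cells (296 CPM), and APELA, a peptide ligand of the apelin receptor (235 and 298 CPM), also had no differentiated read. TRIM60 (475 and 322 CPM), SAMHD1, a nucleotide hydrolase (227 CPM in early passage), and ZNF729 (357 CPM in early passage) stood below 1 CPM. So did SYCP3, a protein of the meiotic chromosome axis (374 CPM in late passage), HMMR, a spindle factor (265 CPM in late passage) and PDCL2 (314 CPM in late passage). The cell cycle list followed: 14 of 15 genes were at least 2-fold lower than in early and 15 of 15 than in late passage (median -3.89 and -4.22 log2, percentile 0.0 in both). CDK1, the kinase of mitotic entry, stood at 11.3 CPM against 923 and 520 CPM. PCNA, the replication clamp, stood at 61.1 CPM against 918 and 861 CPM, and CCNB1, a mitotic cyclin, at 68.1 CPM against 651 and 498 CPM.

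Genes of the mesenchymal and fibroblast list were mostly higher in differentiated cells than in late passage, with a more mixed picture against early passage. Of the 17 genes of the mesenchymal and fibroblast list, 15 were at least 2-fold higher than in late passage (median 6.50 log2, 3.23 to 7.36, or 7.10 with groups without a read at the floor, above all the random lists), and 10 were higher and 5 lower than in early passage (median 1.91 log2, -1.49 to 3.63, percentile 99.98). FN1, which encodes fibronectin, reached 7795 CPM (7758 to 7833) against 81.8 CPM in early and 13.3 CPM in late passage. COL1A2, a chain of type I collagen, reached 1549 CPM against 48.9 and 0.12 CPM. SPARC, a matrix glycoprotein, stood at 1812 CPM against 1006 and 279 CPM, and CALD1, an actin-binding protein, at 1304 CPM against 346 and 126 CPM. COL3A1 and LUM went the other way against early passage, at 82.3 against 419 CPM and 151 against 427 CPM. Without the 13 early passage cells with at least 1000 CPM of COL3A1 or LUM, early passage held 159 and 217 CPM of them. In that alternative, chosen after seeing the data, 11 list genes were at least 2-fold higher and 3 lower than in early passage.

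Among the genes with the largest ratios, AXL, a receptor tyrosine kinase, stood at 7149 CPM in differentiated cells, with a read in each of the 53, against 37.98 CPM in early and 0.07 CPM in late passage. SPP1, which encodes osteopontin, stood at 7650 CPM against 10.9 and 15.7 CPM. KCNJ2, an inward rectifier potassium channel, stood at 741 CPM against 0.34 CPM in early passage and no read in late passage, where the fold is at least 14192. Against early passage the leading genes also held THBS1 (486 CPM against 0.60 CPM), CD44, the hyaluronan receptor (856 against 1.89 CPM), SRPX2 (348 against 0.62 CPM), ACTG2, a smooth muscle actin (534 against 1.65 CPM), COL11A1 (223 against 0.17 CPM), SERPINB5 (192 against 0.07 CPM), TGFBI (198 against 0.10 CPM) and EDN1, the precursor of endothelin 1 (392 against 1.29 CPM). The X-linked KLHL4 (367 against 0.55 CPM) depended on the deepest differentiated cell: its log2 ratio was 7.88 with that cell in the pool and 4.52 without the deepest cell of each group, and that of CD44 was 8.21 and 7.49. Against late passage the leading genes held SOX11 (771 against 0.03 CPM), TAGLN, an actin-binding protein of smooth muscle (938 against 0.33 CPM), CCND2, a G1 cyclin (1625 against 1.36 CPM), PPP3CA, the catalytic chain of calcineurin (882 against 0.42 CPM), VIM, the intermediate filament vimentin (561 against 0.05 CPM), CAV1, the caveola coat protein (617 against 0.26 CPM), and RND3 (559 against 0.09 CPM). Without the deepest cells, RND3 had a log2 ratio of 7.68 in place of 9.01.

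Markers of several other lineages were read as well. In the neural list, 6 of 9 measured genes were at least 2-fold higher than in each naive group (median 1.69 log2, -1.05 to 4.24, and 2.95 log2, 0.05 to 6.36, percentile 99.43 and 99.98), with 2 lower than in early and 1 than in late passage. The higher genes were led by CDH2, which encodes N-cadherin (401 CPM against 59.03 and 0.38 CPM), and MAP2, a neuronal microtubule protein (85.6 CPM against no read and 0.05 CPM). SOX1 had no read in differentiated cells. In the endoderm list, 5 of 7 were higher (median 3.24 and 3.12 log2, percentile 99.99 and 99.80), among them APOA2 (40.8 CPM) and APOA1 (21.3 CPM). GATA6 was lower, at 11.6 CPM against 43.1 and 44.8 CPM. The intervals of the endoderm medians, -1.80 to 5.26 and -1.86 to 5.24, span 0. Trophoblast genes were higher against late passage in 5 of 6, among them KRT7 (101 against 0.19 CPM) and TFAP2A (55.8 against 0.56 CPM), and in 2 of 6 against early passage, with CGA lower in both. Their medians, 3.25 log2 (-3.04 to 6.42) and 0.18 log2 (-5.26 to 2.68), had intervals that span 0. In the early mesoderm list, 2 of 6 genes were higher than in early and 4 of 6 than in late passage, with 1 lower in each. KDR (17.9 CPM against 5.92 and 0.09 CPM) was higher in both, and HAND1 (35.8 CPM against 20.4 and 1.81 CPM) by at least 2-fold against late passage alone, but the median against early passage, 0.58 log2, was -1.95 in the 7 differentiated cells of a stricter cell filter. The primed list, genes of the later epiblast-like state, had 5 of 10 higher than in early and 8 of 10 than in late passage (percentile 98.90 and 99.46). With 1 and 2 genes lower, the intervals of its medians, -0.58 to 6.18 and -1.445 to 6.275, span 0. SOX11 led it, while DNMT3B stood at 21.6 CPM against 68.9 and 108 CPM. Among epithelial genes, KRT18 (1844 CPM against 764 and 162 CPM) was at least 2-fold higher and EPCAM (203 CPM against 443 and 414 CPM) lower in both comparisons, and KRT8 (1009 CPM against 524 and 104 CPM) passed 2-fold against late passage only. In that list, 3 genes were at least 2-fold higher and 3 lower than in early passage (6 and 2 under TMM, 6 and 1 under DESeq2 scaling), and 6 higher and 3 lower than in late passage. Of 6 measured endothelial and blood genes, 3 were higher and 3 lower than in early passage, and 3 higher and 1 lower than in late passage, with CD34 at 25.8 CPM in the pool but a read in only 5.7% of cells.

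Glycolytic genes were higher in differentiated cells in 7 of 13 against early and 8 of 13 against late passage, with 2 lower in each, or 10 higher and none lower than in early passage under DESeq2 scaling (median 1.02 and 1.86 log2, percentile 98.41 and 99.78). GAPDH, which has many processed pseudogenes, stood at 4841 CPM against 948 and 1064 CPM, ALDOA at 1761 CPM against 546 and 483 CPM, and ENO1, an enolase, at 1639 CPM against 1129 and 840.5 CPM. Genes of DNA methylation went both ways. DNMT3A, a de novo methyltransferase, stood at 557 CPM against 31.6 and 41.5 CPM, whereas TET1, which oxidises methylcytosine, stood at 8.15 CPM against 613 and 749 CPM. Of the 9 genes of this list, 1 was higher and 5 were lower in each comparison. Of the 14 immediate early and stress genes, 5 were higher and 5 lower than in early passage, and 8 higher and 3 lower than in late passage. Their median against early passage, 0.29 log2, was -0.16 as a mean of cells and -0.29 without the deepest cells. MDM2, a p53 target, stood at 3452 CPM against 891 and 708 CPM. The imprinted list split into 6 higher and 5 lower against early and 5 higher and 4 lower against late passage, with MEST at 1005 CPM against 502 and 251 CPM and MEG3 at 116 CPM against 612 and 285 CPM. Its median against late passage, -0.05 log2, was 0.07 under TMM and 0.16 under DESeq2 scaling. Of 8 measured HOX genes, HOXA3 alone was higher against early passage (15.1 against 0.08 CPM) and 5 were lower, among them HOXB2 (no read against 48.98 CPM). Against late passage, 1 was higher and 4 were lower. In the 7 differentiated cells of the stricter filter, list medians also turned for early mesoderm against late passage (2.71 log2 to -0.13), for endothelial and blood genes against early (0.38 to -0.88) and late passage (1.47 to -0.32), and for imprinted genes against early passage (0.68 to -0.97).

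**Figure D1:**
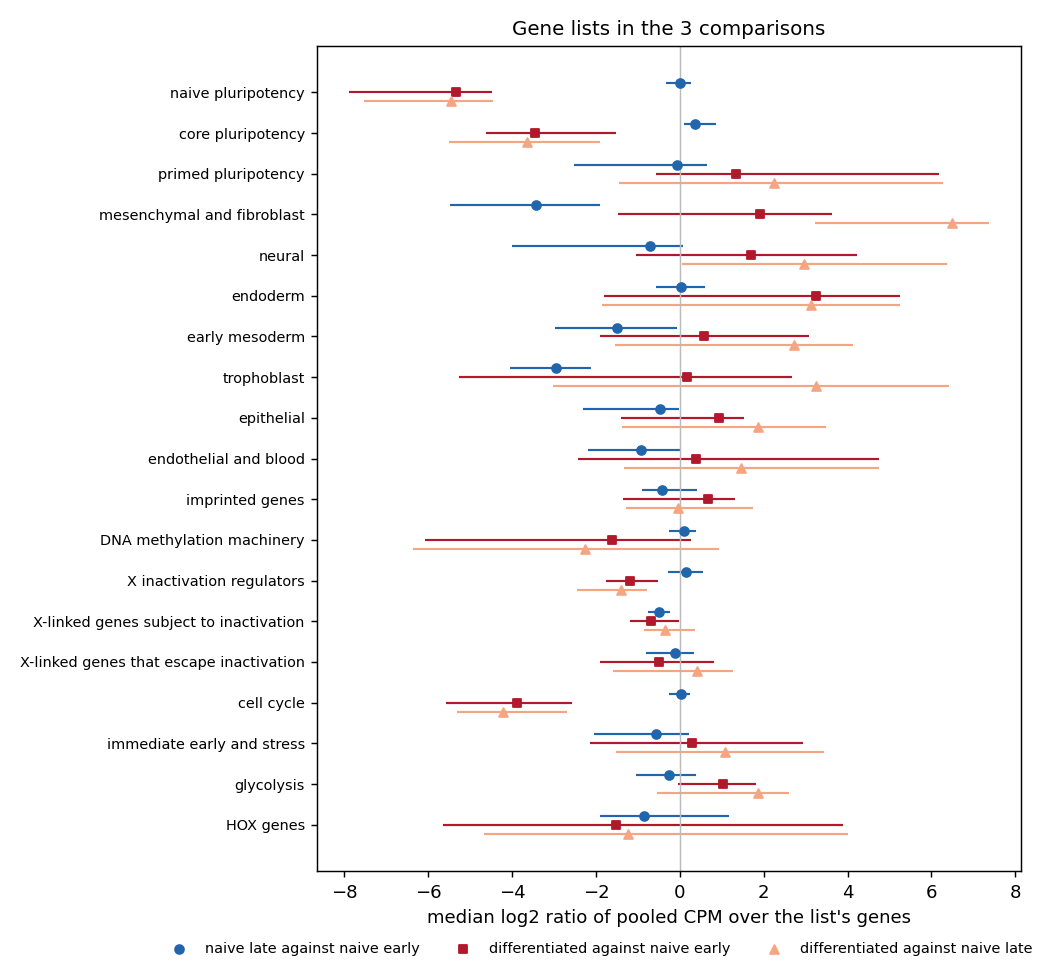
Median log2 ratio of pooled CPM (pseudocount 1) over the measured genes of each of the 19 fixed lists, in 3 comparisons given by colour and marker. Bars are 95% order-statistic intervals over the genes of a list, not over samples. The naive list lies at -5.34 and -5.46 in the comparisons of differentiated cells and at 0.00 between the passages.

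The passage comparison asks whether naive cells differ with time in culture. The naive programme itself stood level between passages: the median log2 ratio of the 19 naive genes, late against early passage, was 0.00 (-0.34 to 0.26, percentile 59.85), with 1 gene at least 2-fold higher (MAEL) and 2 lower (KLF17 and FGF4); under DESeq2 scaling the median was 0.33, as much as the autosomal median itself moves under that scaling (0.33). DNMT3L, KHDC1L, DPPA5 and DPPA3 had a read in every kept cell of both groups. Core pluripotency genes had a median of 0.36 log2 (0.10 to 0.87, percentile 97.43). DPPA2, at 158 against 34.9 CPM, and GDF3, a ligand of the Nodal family at 190 against 91.4 CPM, were higher in late passage, with LIN28A as the last of the 3 genes at least 2-fold higher. PRDM14, at 44.3 against 113 CPM, was lower. The cell cycle list stood at 0.02 log2, or -0.05 without the deepest cells, with BIRC5 alone at least 2-fold higher and CDK1 at 520 against 923 CPM.

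Genes of lists for other cell types set the passages apart, without showing whether other cells or the naive cells made these transcripts. Of 17 mesenchymal genes, 16 were at least 2-fold lower in late passage (median -3.44 log2, -5.48 to -1.90, percentile 0.0, or -4.80 with groups without a read at the floor), and 16 still were without the 13 early passage cells with at least 1000 CPM of COL3A1 or LUM, an alternative chosen after seeing the data. COL3A1, a chain of type III collagen, stood at 419 CPM in early passage, with a read in 80 of 87 cells, and had no read in late passage, at least 8029-fold less. LUM, the matrix proteoglycan lumican, stood at 427 CPM in 81 of 87 early passage cells and at 0.05 CPM in late passage. SPARC stood at 279 against 1006 CPM. Each of the 6 measured trophoblast genes was at least 2-fold lower in late passage (median -2.94 log2, percentile 0.0), among them CGA, the common chain of glycoprotein hormones, at 7.20 against 37.3 CPM. KRT18 (162 against 764 CPM) and KRT8 (104 against 524 CPM) went with them, as 2 of the 3 epithelial genes lower in late passage. Of the neural, early mesoderm and endothelial lists, 4 of 9, 3 of 6 and 2 of 6 genes were lower in late passage. Their medians lay at percentile 9.97, 3.21 and 14.71, less far from matched random lists. None of the 7 endoderm genes differed by 2-fold (median 0.02 log2, -0.30 as a mean of cells). Of the 9 neural genes, 1 was higher. Of 14 immediate early and stress genes 1 was higher and 5 were lower, among them CDKN1A, a cell cycle inhibitor (18.04 against 263 CPM). Of the other lists, the primed list had 1 gene higher and 3 lower, glycolysis 3 lower (median -0.25 log2, but 0.09 under DESeq2 scaling), imprinted genes 2 higher and 1 lower (none lower under TMM or DESeq2 scaling), DNA methylation 1 lower (none under TMM, DESeq2 scaling or as a mean of cells, nor without the deepest or the collagen-rich cells) and HOX genes 1 higher and 3 lower.

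The other genes lowest in late passage were read in many early passage cells: RHOBTB3 (169 CPM in early against 0.14 CPM in late passage), NPNT, a matrix ligand of integrins (132 CPM against no read), MMP12, a macrophage elastase (130 CPM against no read), MME, the peptidase neprilysin (108 CPM against no read), the X-linked HS6ST2 (91.3 against 0.02 CPM), NPPB, a natriuretic peptide (88.9 against 0.05 CPM), CCKBR (93.7 against 0.49 CPM), PTPRD (62.1 against 0.05 CPM), TM4SF1 (58.6 CPM against no read) and LOX, which crosslinks collagen (54.9 CPM against no read). Genes higher in late passage differed less. They were led by ZNF239 (90.9 against 3.18 CPM), the X-linked FAM133A (62.9 against 2.45 CPM, in 90.1% against 11.5% of cells), ZNF716 (28.96 against 1.29 CPM), ANKRD55 (29.5 against 2.91 CPM), COX7B2 (78.1 against 9.78 CPM), PHF11 (62.8 against 8.17 CPM), SPA17, a sperm surface protein (42.96 against 5.14 CPM), ABHD14B (27.5 against 3.05 CPM) and ADAM18 (23.1 against 2.30 CPM). The antisense transcripts PAX8-AS1 (28.9 against 3.06 CPM) and NUP50-AS1 (30.8 against 3.62 CPM) overlap other genes and are uncertain, as the strand setting of the counting is not given in the sources used here. Without the deepest cell of each group, the log2 ratio of ZNF239 was 2.64 in place of 4.46, that of ANKRD55 1.49 in place of 2.96, that of PHF11 1.85 in place of 2.80 and that of MME -5.99 in place of -6.77. With each cell weighted alike, the log2 ratio was 0.88 for PHF11 and 0.82 for NUP50-AS1, both below 2-fold, 1.59 for SPA17, 1.61 for ABHD14B and 2.22 for ZNF239.

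The series title names dampening of the X chromosome, a lowering of X-linked expression without silencing of a whole chromosome. X-linked genes were lower in late than in early passage naive cells. The median of 310 X-linked genes lay 0.52 log2 below that of 7968 autosomal genes (shift -0.52, interval -0.69 to -0.35, or -30.4% relative to autosomes), and no random autosomal list of matched expression reached as low (percentile 0.0). Of the 310 genes, 222 lay below the autosomal median, where 104 lay at least 2-fold below it and 14 at least 2-fold above. No autosome moved as far: the 22 autosomes ranged from -0.14 (chromosome 19) to 0.13 (chromosome 9). Per cell, X-linked genes took a median of 4.21% of reads in early passage (quartiles 4.01% and 4.53%) and 3.60% in late passage (3.31% and 3.81%), and 96.3% of late passage cells lay below the median early passage cell. The median X-linked gene stood at 51.1 CPM and the median autosomal gene at 48.2 CPM in early passage, against 29.5 and 40.9 CPM in late passage.

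Sets of X-linked genes were also taken apart, with no test of a difference between them. In the hand list of genes subject to X inactivation, 58 genes passed the expression minimum and shifted by -0.30 (-0.52 to -0.05), among them PLS3, an actin bundler (805 against 1529 CPM), and against it COX7B (1483 against 910 CPM) and NDUFA1, both of the respiratory chain (1923 against 939.5 CPM). Of the 62 genes measured in that list, 1 was at least 2-fold higher and 13 were lower in late passage, or 4 and 5 under DESeq2 scaling. The 19 genes of the escape list, which are transcribed from the inactive X as well, shifted by 0.00 (-0.69 to 0.59), with KDM6A, a histone demethylase, at 64.1 against 172 CPM and EIF1AX at 1406 against 888 CPM. Of 20 measured, none was at least 2-fold higher and 4 were lower (2 and 1 under TMM, 3 and 1 under DESeq2 scaling), and the median of -0.11 log2 was 0.13 under TMM and 0.20 under DESeq2 scaling. With every gene that had a read, low ones included, the X shift was -0.25. Regulators of X inactivation other than XIST were level, with 9 of 10 within 2-fold, such as HNRNPU (909 against 617 CPM) and RLIM (348 against 413 CPM).

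**Figure D2:**
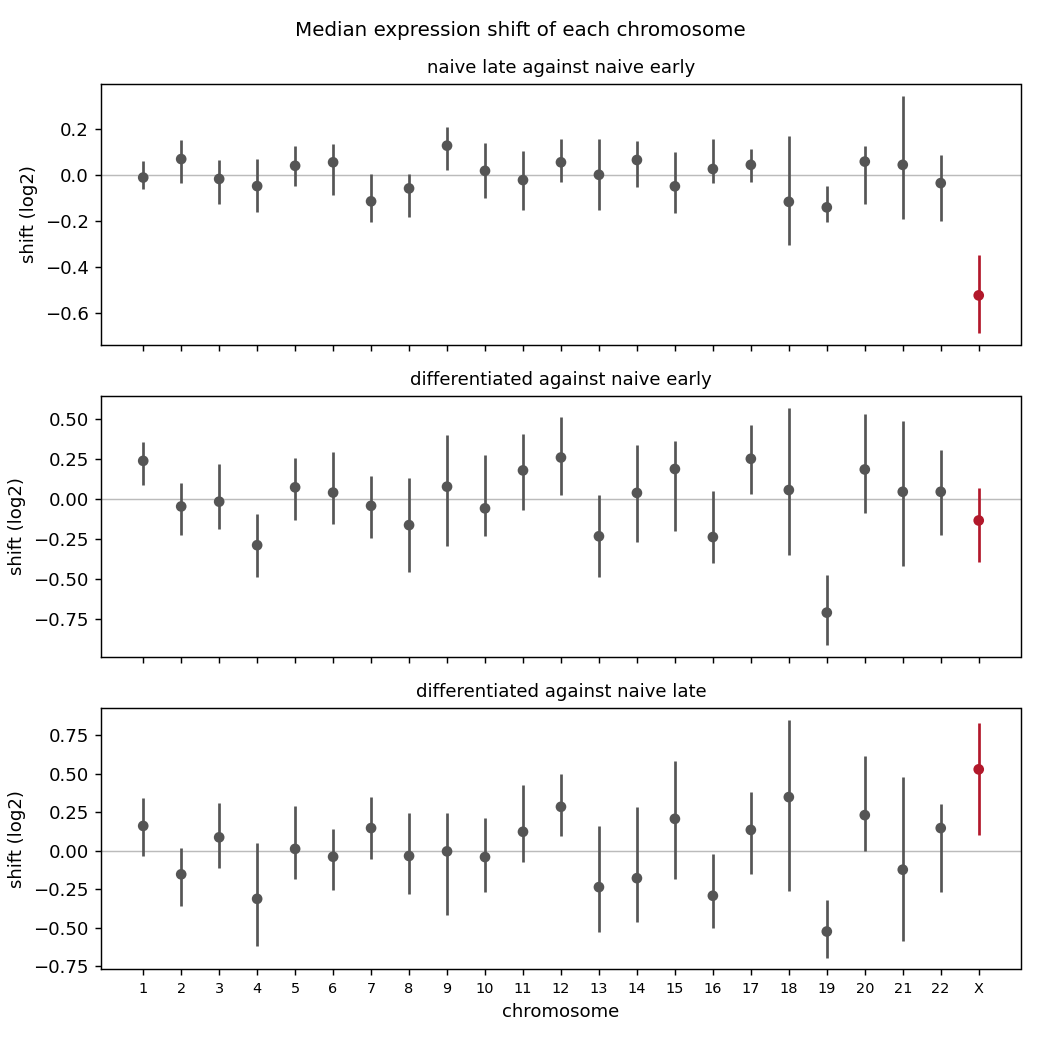
Shift of the median log2 ratio of each chromosome's genes from the median of all autosomal genes, by chromosome (x axis), in 3 comparisons (panels), with the X in red. Bars are 95% order-statistic intervals over genes. Between the passages the X lies at -0.52 and the autosomes lie from -0.14 to 0.13.

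XIST, the noncoding RNA that coats the X chromosome during inactivation, was read in most naive cells and more often at the late passage. At least 1 read was found in 79 of 81 late passage cells (97.5%, interval 91.4% to 99.7%) and in 76 of 87 early passage cells (87.4%, 78.5% to 93.5%). With each cell thinned to 100000 gene reads the shares were 96.3% (89.6% to 99.2%) and 64.4% (53.4% to 74.4%). At 10 CPM or more they were 96.3% and 51.7%. The pooled level was 718 CPM in late (711 to 725) and 336 CPM in early passage (332 to 339), a ratio of 2.14 (2.11 to 2.17, counting error only). In the differentiated group, 19 of 53 cells had a read (35.8%, 23.1% to 50.2%), 34% after thinning, and the pool held 56.7 CPM (53.5 to 60). This last group was not counted alike: its files list TSIX, the antisense partner of XIST, and the naive files do not, so reads in the shared part can drop out as ambiguous in the differentiated files alone. The longest XIST transcript lies inside TSIX over 38.9% of its bases (GENCODE 29), and its last 3000 bases wholly.

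The X of differentiated cells was set against each passage. Against late passage the X shift was 0.53 (0.10 to 0.83, percentile 100), with no autosome as far from the autosomal median, while chromosome 19 stood at -0.52 and chromosome 18 at 0.35. That margin was narrow: 3 autosomes lay as far under the stricter filter with 7 differentiated cells, 1 did as a mean of cells, and the hand list of genes subject to inactivation shifted by 0.025 (-0.49 to 0.72). The stricter filter also widened the interval of the X shift to -0.04 to 1.18. With no gene filter the shift was 0.025 (0.025 to 0.025), a median set by genes with tied ratios, which says little about the X. Against early passage the X shift was -0.14 (-0.39 to 0.07, percentile 20.94), and 11 of the 22 autosomes lay as far or farther, so an X shift was not detectable. The list of genes subject to inactivation shifted by -0.09 (-0.60 to 0.64) there. The X-linked share of reads spread more widely between differentiated cells, with a median of 3.96% and quartiles of 3.28% and 4.57%. Single X-linked genes stood apart in both directions. Of the 62 measured genes subject to inactivation, 8 were at least 2-fold higher and 26 lower than in early passage, or 15 and 14 under DESeq2 scaling. Against late passage 15 were higher and 18 lower, or 16 and 16 under TMM and 17 and 12 under DESeq2 scaling. Of the 20 escape genes, 5 were higher and 7 lower than in early passage (median -0.49 log2, but 0.10 under DESeq2 scaling) and 6 higher and 6 lower than in late passage. EIF2S3, a translation initiation factor of the escape list, stood at 5068 CPM against 411 CPM in early and 498 CPM in late passage, and RPS4X at 1107 CPM against 469 and 628 CPM. PLS3 stood at 1026 CPM against 1529 and 805 CPM, and DDX3X at 425 CPM against 984 and 835 CPM. Regulators of X inactivation other than XIST were at least 2-fold lower in 7 of 10 against early and 8 of 10 against late passage, RLIM at 122 CPM among them. The list's medians, -1.19 and -1.40 log2, lay at percentile 17.26 and 10.56, so random lists of matched expression often fell as low. Under DESeq2 scaling, which raises the median autosomal log2 ratio by 0.57 and 0.25 in these comparisons, 2 and 6 of the 10 were lower.

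**Figure D3:**
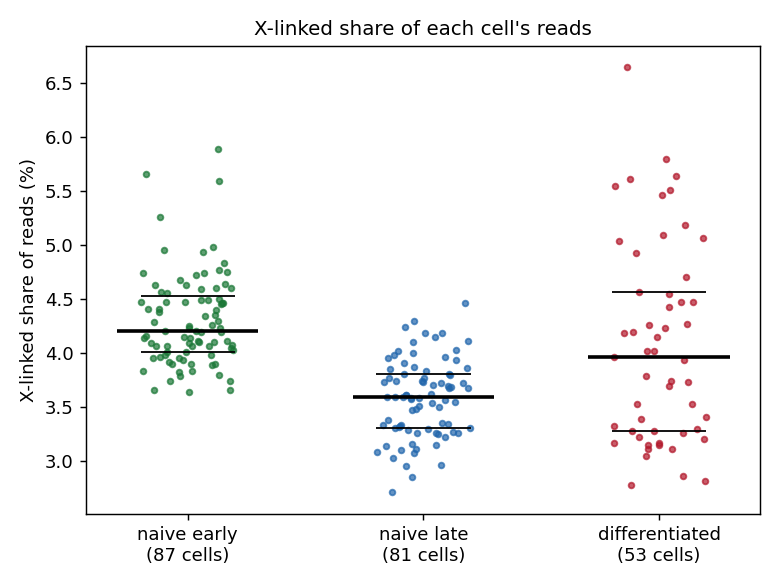
Share of each kept cell's reads on X-linked genes other than XIST, in percent of X-linked plus autosomal reads, with 1 point per cell, a thick line at the median and thin lines at the quartiles. Medians are 4.21% in 87 early passage, 3.60% in 81 late passage and 3.96% in 53 differentiated cells.

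Clustering within groups gave 3 clusters of differentiated cells (21, 17 and 15 cells), 4 of late passage cells (29, 19, 17 and 16) and 3 of early passage cells (31, 29 and 27). Each naive cluster detected at least 6 of the 7 naive markers, and no marker of another lineage was among its 10 leading genes. All 3 early passage clusters also detected 4 of 7 mesenchymal markers (COL1A1, COL1A2, COL3A1 and LUM) and 1 to 3 of 7 trophoblast markers. Cluster 1 of each group held the most reads and the fewest genes per cell, with median reads 1.21, 1.57 and 1.71 times the group median in differentiated, late and early passage cells. NEAT1, a noncoding RNA of nuclear paraspeckles, was among the leading genes of 1 naive cluster, cluster 3 of late passage (3510 against 204 CPM). None of the differentiated clusters detected a naive marker. The cluster of 17 differentiated cells was led by FLT1, a VEGF receptor (265 CPM against 1.90 CPM in the other cells), WISP1 (95.5 against 0.20 CPM), SULF1 (107 against 0.40 CPM) and GREM1, a BMP antagonist (163 against 3.90 CPM), and it detected 5 of 7 mesenchymal markers (COL1A1, COL1A2, COL3A1, LUM and TWIST1). LGALS1, a galectin of the mesenchymal gene list (121 against 1.40 CPM), was among its 10 leading genes. The clusters of 21 and 15 differentiated cells each detected 3 of 7 mesenchymal markers. They detected 4 and 3 of 7 trophoblast markers, against 1 of 7 in the cluster of 17. As none of the markers set for naming cell types was among the 10 leading genes of a cluster, the clusters stay unnamed. Their number depended on the settings, with 2 differentiated clusters at Leiden resolution 0.5 and 4 with 2000 variable genes.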

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

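The library whose labels conflict was left out of the main comparisons, and it held reads of the naive list: 1372 of its 104575 gene reads fell on the 19 genes of the naive list, above the 3 reads that a count of 0 would allow. That is 13120 CPM, against 115.8 CPM in the differentiated, 8010 CPM in the late passage and 7522 CPM in the early passage pool. Of those genes, 17 had a read, among them KHDC1L (391 reads), DPPA5 (238 reads) and DNMT3L (197 reads), whereas differentiated cells had a read in a median of 1 and at most 5 of them, and late and early passage cells in a median of 16 each. FN1, AXL, COL1A2, COL3A1 and LUM had no read in it. Across genes, which are not independent replicates, its counts had a Spearman correlation of 0.705 with the late passage pool, 0.640 with the early passage pool and 0.290 with the differentiated pool.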

How the results depend on the processing

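The alternatives without the deepest cells, with thinned cells in pools or without collagen-rich cells, the stricter cell filter for named genes, and all those for lists other than the naive and X-linked lists were chosen after seeing the data. No paired analysis was possible because each group is taken as 1 culture and well names do not link cells across groups. Between passages, the X shift kept its sign in all 18 alternatives (-0.61 to -0.25). It left the main interval for -0.25 with no gene filter and -0.30 with the inactivation list only. Differentiated against late passage it ranged from 0.025 to 0.64, with 0.025 under each of those same settings. With no gene filter, that value was set by genes with tied ratios. Against early passage it stayed inside its interval in 17 of 17 (-0.22 to 0.04). The number of autosomes as far from the median as the X, differentiated against late passage, went from 0 to 1 without a cell filter, to 3 with the stricter filter and to 1 for the mean of cells' CPM.

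Of the shares of cells with XIST, the differentiated share was 14.3% (0.4% to 57.9%) in the 7 cells of the stricter filter and 11.1% (0.3% to 48.2%) in the 9 cells thinned to 500000 reads. The early passage share was 51.7% at 10 CPM, 64.4% thinned to 100000 reads, 68.5% thinned to 500000 reads and 95.2% in well columns 7 to 12. The late passage share was 100% in columns 1 to 6. The naive list stayed between -7.55 and -4.39 against early passage, the latter with a pseudocount of 5, and between the passages reached 0.33 under DESeq2 scaling. Of 272 medians of the other lists, 267 stayed inside their intervals. The stricter filter gave -1.95 for early mesoderm, -1.84 for X inactivation regulators and -5.67 for the cell cycle (differentiated against early), and DESeq2 scaling gave 0.43 for DNA methylation and 0.31 for the cell cycle between passages. The difference in X share between XIST classes was -0.91 percentage points in differentiated and -0.23 in early passage cells as a mean over cells, and -0.15 in early passage at 100 CPM. At Leiden resolution 0.5 late passage clusters numbered 2 in place of 4 and differentiated clusters 2 in place of 3; with 2000 variable genes differentiated clusters numbered 4. The 24 named genes of each comparison kept their sign, which was hardly open since they were chosen for extreme ratios. For all of these, the cause was not tested. Depth limits the differentiated group most, with 53 cells and 21110440 reads.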

Other observations

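The tests of stretches of the X, of ambiguous reads and of the early passage group without collagen-rich cells, the limit of 1000 CPM for those cells, and the sets of zinc finger genes were chosen only after the result was seen, and so was the bound that turned the planned share of cells with XIST in thinned reads into a test of depth. Zinc finger genes of chromosome 19 were lower in differentiated cells, with no test of a difference from other sets. Chromosome 19, which carries large clusters of genes for KRAB zinc finger proteins, repressors of transposable elements, had the lowest median of the autosomes, at -0.71 log2 against early and -0.52 against late passage. Its 183 genes named ZNF lay 1.24 log2 below the autosomal median against early passage (shift -1.24, -1.59 to -0.82), with 100 of them at least 2-fold below it and 20 above. Its 310 other genes shifted by -0.40 (-0.67 to -0.12), and 141 ZNF genes on other autosomes by -0.65 (-1.10 to -0.23). Against late passage the same sets shifted by -0.79 (-1.19 to -0.51), -0.31 (-0.56 to -0.10) and -0.32 (-0.69 to 0.13), with intervals that overlap. Between the passages, ZNF genes shifted by -0.32 (-0.53 to -0.17) on chromosome 19 and by -0.27 (-0.38 to -0.15) elsewhere. The other genes of chromosome 19 shifted by -0.04 (-0.14 to 0.03). Against early passage and between the passages, the intervals of ZNF and other genes of chromosome 19 do not overlap.

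Within groups, cells were parted by XIST. Among differentiated cells, X-linked genes took 3.42% of reads (3.40% to 3.43%) in the 17 cells with at least 10 CPM of XIST and 4.49% (4.48% to 4.502%) in the 34 cells with no read, a difference of -1.08 percentage points, with 2 cells between. Median depth was 286113 and 340936 gene reads. These intervals cover counting error only, and single differentiated cells ran from 2.78% to 6.64%. The share is a sum of reads, so a few X-linked genes with many reads, such as EIF2S3 in this group, can weigh heavily. The classes were not compared gene by gene or within clusters, so a shift along the whole X is not shown. In this group XIST reads can drop out as ambiguous with TSIX, so some cells with no read may be misplaced. Among early passage cells the shares were 4.20% in 45 cells and 4.32% in 11 cells, with 31 cells between, a difference of -0.12 points (-0.23 as a mean over cells) and median depths of 513014 and 731486 gene reads. Late passage cells were not parted, as 2 had no read. The classes are ranges of a measured value, not cell types.

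The lower X in late passage has technical explanations that the tables argue against. Between 72 late and 72 early passage cells matched in depth, with medians of 481158 and 521722 gene reads, the X shift was -0.52 (-0.67 to -0.33), below every autosome, and against only the 43 early passage cells lowest in COL3A1 plus LUM it was -0.49 (-0.70 to -0.29), although COL3A1 there stood at 64.5 CPM in place of 419 CPM. In the 4 least shifted of 8 stretches of the X, by gene order in GRCh38.p14, it was -0.42 (-0.66 to -0.25), below every autosome, so a single segment could not account for it. In X-linked share of reads, 96.3% of late passage cells lay below the median early passage cell. The lowest late passage cell, at 2.715%, lay above 0.5 of the early passage median of 4.21%. Single early passage cells ran from 3.639% to 5.885%, so that comparison cannot decide whether any cell lost an X. A dampening that grows with passage is a hypothesis these values fit, and a lost or silenced X, different cell lines or cultures and effects of the capture run stay open as untested, since alleles were not analysed here.

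Low XIST in the differentiated group was not accounted for by depth: at 100000 gene reads per cell 34% of cells had a read (21.5% to 48.3%), below the early passage interval of 53.4% to 74.4%. Whether reads were set aside as ambiguous where TSIX is listed cannot be told apart from lower expression. The differentiated pool would lack 279 CPM of XIST against early passage, and its ambiguous reads over all genes amount to 31491 on the same scale (33972 in early and 41990 in late passage), far more than could be resolved. Lower expression after differentiation may hold as well, untested.

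Mesenchymal transcripts in early passage were not carried by a few cells alone: without the 13 cells with at least 1000 CPM of COL3A1 or LUM, 16 of the 17 list genes were still at least 2-fold lower in late passage, with COL3A1 at 159 CPM and a read in 90.5% of the remaining cells. RNA of those 13 cells spread over the others is a candidate source. For 106 genes high in those cells, the level in the other cells was a median 20.4% of theirs, with an upper quartile 2.25 times the lower, inside the bound of 4 set in advance. Own expression graded between cells could give a ratio inside that bound too, as the 13 cells were set by a limit of 1000 CPM. The bound therefore cannot decide between spread RNA and own expression, and no conclusion is drawn from it. Another comparison was added after that ratio was seen. Among 8 mesenchymal list members the share ran from 2.63% (COL1A2) to 38.4% (VIM). Choosing the 13 cells by COL3A1 or LUM can itself lower the shares of genes that vary with these, so this range cannot decide either. The 13 cells also held 66.3% of the naive list's CPM in the others, so no pure source profile exists here, and spread RNA and own expression cannot be told apart.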
